A study of Drosophila melanogaster with 2 samples.

How the data were processed

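Chromatin from whole testes of adult w1118 males was compared between an immunoprecipitate of dBigH1 and its input DNA, with 1 library of each. dBigH1 is the germline-specific linker histone H1 variant of Drosophila melanogaster, encoded by BigH1 (listed as CG3509). Per the labels' protocols, 2000 testes were dissected and fixed, accessory glands were removed by hand, pools of 1000 testes were sonicated to fragments of 200 to 500 bp, and libraries were made from 3.5 ng of DNA with size selection to 300 to 350 bp and 18 PCR cycles. Single reads of 50 nt were sequenced on a HiSeq2000. Per the submitters' processing notes, CASAVA 1.9, Bowtie2, FastQC 0.10 and R 2.15 were used with genome build dm3. How reads were assigned to genes and how reads with several matches in the genome were treated is not given in the sources used here.

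The deposited table held 15421 FlyBase genes, with coordinates, gene length, 1 log2 RPKM value per library and a column headed as a MAnorm log2 fold change. Per the file headers, the authors gave log2 RPKM values, where RPKM is reads per kb of gene scaled to library size. Only after 1 was subtracted from the exponentiated value did the numbers become whole reads: 100% of values in both libraries were whole within 0.01 read, against 1.99% of input values and 2.00% of dBigH1 values with no offset. The values were therefore read as log2(RPKM + 1). The size of 1 read gave library totals of 12747726 reads for input and 2864636 for dBigH1, a depth ratio of 4.45. Every listed gene had at least 1 read in each library, and a list restricted in this way raises the ratios of short genes with few reads.

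The plan fixed before the data were examined named the deposited MAnorm column as the main ratio if the table had one. The deposited MAnorm column turned out to be a standardized score, with a mean near 0, an SD of 0.999 and a range from -3.56 to 7.66, not a log2 fold change as its header says. After its values were seen it was therefore used as an alternative, in score units, and the plan's fallback, log2((dBigH1 RPKM + 1)/(input RPKM + 1)), became the main ratio. Across genes, Spearman's rho between the score and this ratio was 0.877. A pseudocount of 1 understates the change of genes with low RPKM. Genes with an RPKM of at least 1 in either library entered, which left 15419.

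The median ratio was -0.85 on the log2 scale, and values are given relative to this median gene. No p-value was computed, since each group had 1 library. For single genes, the log2 ratio of recovered reads, scaled by library totals and set against the median ratio of reads of all genes, is given with a 95% exact Clopper-Pearson interval for the share of reads from dBigH1. Medians of groups carry a counting SD from 100 Poisson resamplings of the reads. Reads were not marked with molecular identifiers, so intervals and SDs cover counting error only. Genes with overlapping coordinates share reads: in each of the 120 sets of genes with identical coordinates all members had the same reads, and 41.5% of genes overlapped another gene.

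For 18 gene lists fixed before the data were examined, the list median was set against 10000 random lists of the same size, matched in 20 classes of the mean log2 value of both libraries, and its percentile was recorded. A list was called above or below random lists outside percentiles 2.5 to 97.5. Percentiles were recomputed with matching on input RPKM and on gene length. Chromosome groups were compared as medians against genes on arms 2L, 2R, 3L and 3R. Genes named in the text were the 10 highest and 10 lowest ratios among genes with a symbol, BigH1, the His1 copies, bam, bgcn, tut, mei-P26, vas, nos, aly and can, and the highest and lowest member of each list. Any other named gene or group was chosen after its values were seen. Unless stated otherwise, ranks and group medians use the main ratio, while values of single genes are read ratios, on which order can differ.

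Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, an RPKM of at least 5 in both libraries, centring on the median gene, a 2-fold threshold, the MAnorm score, means in place of medians, and the other matchings. Others were added later and are marked as such where they are reported. The design text names peak calling, but regions called as peaks were not analysed here, and GC content was not tested because a genome sequence was not used here. A RefSeq table for Release 6 of the assembly was used for gene names only and matched 13050 genes.

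The same functions were tested on simulated reads for all 15421 genes, drawn from the input counts and library sizes with 200 genes changed. Reads and totals were recovered exactly from the log2 values. Of genes raised 2-fold, 90.0% passed 1.5-fold, as did 100% of those raised 4-fold. Of genes lowered to 0.5 of the level, 76.0% passed, and 96.0% of those lowered to 0.25. Among unchanged genes 9.70% passed by counting noise, and 96.2% of the intervals held the true ratio. Of 200 lists of 20 genes drawn at random, 4.00% lay outside the limits, and a list of 20 genes raised 2-fold lay at percentile 100. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.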

Results

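The genomic distribution of dBigH1, the germline linker histone of Drosophila, was profiled by ChIP-seq in whole testes of adult w1118 males and compared with input DNA from the same tissue. There was 1 dBigH1 library and 1 input library, so no value has a replicate check, and every comparison below describes these 2 libraries. The input library held 12747726 reads and the dBigH1 library 2864636. Reads counted in genes amounted to 63.4% of the input total and 41.6% of the dBigH1 total, with reads in overlapping genes counted in each. The median gene had 197 input reads and 20 dBigH1 reads, and 23.3% of genes had fewer than 10 dBigH1 reads, so for many single genes only large differences were detectable.

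The comparison of dBigH1 with input asked which genes carried more or less dBigH1 signal than their DNA content gave. The gene encoding dBigH1 itself, BigH1 (FBgn0038252, chromosome 3R, 10489165 to 10490544, build dm3), had 439 dBigH1 reads against 168 input reads. Its RPKM was 111 in the dBigH1 library and 9.55 in input, and its read ratio was 23.3-fold above that of the median gene (95% interval 19.5 to 28.0). The eye colour transporter gene w (FBgn0003996, chromosome X, 2684632 to 2690499) stood higher, with 1408 dBigH1 reads against 248 input reads. Its RPKM was 83.8 against 3.32, and its read ratio was 50.7-fold above the median gene (44.3 to 58.3). These were the 2 highest RPKM ratios among genes with a symbol. The next by RPKM ratio was Sirt6, which encodes a sirtuin, with a read log2 ratio of 2.81 above the median gene (2.63 to 2.99).

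**Figure D1:**
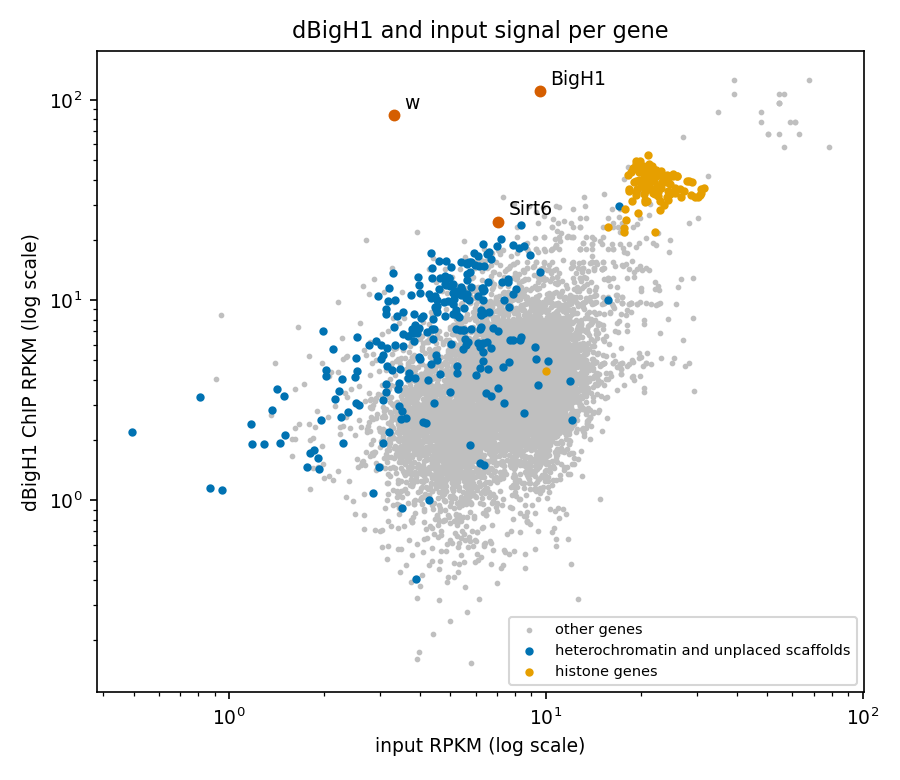
dBigH1 ChIP RPKM (vertical, log scale) against input RPKM (horizontal, log scale), 1 point per gene, with genes on heterochromatin and unplaced scaffolds in blue, histone genes in orange and 3 named genes in red. BigH1 and w lie far above the other genes at their input RPKM of 9.55 and 3.32.

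Other genes with the highest ratios were CG32795, next to w, at 2.76 above the median gene on the log2 scale of reads (2.54 to 2.97), and baf, which encodes a DNA-binding protein of the nuclear envelope, at 2.47 (2.09 to 2.86). CG42857 was at 2.42 (1.89 to 2.94). CG40204, on an unplaced scaffold, was at 2.84, but on 8 dBigH1 reads (1.29 to 4.33). The remaining 3 of the 10 highest were copies from the histone cluster, His1:CG33840, His1:CG33834 and His2A:CG33814, at 2.38, 2.34 and 2.33. The 10 lowest genes had 1 to 3 dBigH1 reads each. nero, which encodes deoxyhypusine hydroxylase, had 1 dBigH1 read against 175 input reads, a read log2 ratio of -4.29 relative to the median gene (-9.60 to -1.80). CG34125 had 1 against 111 (-3.64, -8.95 to -1.13). The co-chaperone gene Sgt1 had 2 against 162 (-3.18, -6.24 to -1.31), and Elba2, listed as CG9883, had 3 against 201 (-2.91, -5.20 to -1.34). For aust, a male-meiosis gene related to borealin, the ratio was -2.85 (-5.91 to -0.97). mRpL34, which encodes a mitochondrial ribosomal protein, was at -2.86 (-8.19 to -0.33) and the cuticle gene Cpr78Cc at -3.18 (-8.50 to -0.66). CG10674, CG17327 and CG12321 were at -3.07, -2.75 and -2.75, all with intervals below 0.

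Across all 15419 genes, 444 lay at or above 1.5-fold and 10942 at or below it, so that 3.90% of the genes beyond the threshold were higher. This split depended on the scaling between libraries. Relative to the median gene, 1986 genes were higher and 1780 lower, or 52.7% higher. Counting noise alone, simulated with no gene changed, gave 471 higher and 790 lower genes relative to the median. Every gene was placed at the ratio of summed reads, which gives a typical gene more dBigH1 reads than it had and so understates noise. Simulated genes could also lack reads, unlike the listed genes. The simulated counts are therefore not directly comparable with the observed ones. The 95% interval of the read ratio lay wholly above the median gene for 2760 genes (17.9%) and wholly below it for 1451 (9.41%). The nominal level for counting error alone is 2.5% on each side. Scatter from PCR and the restriction to genes with at least 1 dBigH1 read also enter, so the excess over that level was not assigned to dBigH1.

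Histone genes as a group had the highest median of the gene lists with a pseudocount of 1, while with 0.1 the Y-linked list was higher, at 1.80 against 1.75. Of 112 replication-dependent and variant histone genes, 111 were at least 1.5-fold above the median gene, and the list median was 1.59 above it (counting SD 0.04), above all random lists matched on mean signal, input RPKM or length. The exception was the variant gene His2Av on 3R, at -0.17 (-0.83 to 0.42). The 23 copies of His1, which encodes the somatic linker histone, had a median log2 RPKM ratio of 1.98 above the median gene (1.66 to 2.18 over copies). The values of 2.38 and 2.34 given above for His1:CG33840 and His1:CG33834 are read ratios, a different scale. Median RPKM of the His1 copies was 45.5 in dBigH1 and 19.7 in input. The copies are near-identical in sequence, so reads could have been divided among them, and the values of single copies are uncertain. The named histone copies among the highest genes lie in a cluster on 2L. Random lists drew separate genes, so they do not show how unusual such a cluster is. On the MAnorm score the histone list lay 0.36 above the median gene and was no longer the highest. Several lists stood above it there, led by the Y-linked list at 2.64 and the pericentromeric list at 1.84.

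Genes of the Y and of heterochromatin were also higher. All 6 Y-linked fertility genes that passed the filter were at least 1.5-fold above the median gene, with a list median of 1.38 (counting SD 0.08) and percentile 100 among random lists. kl-2, a dynein heavy chain gene needed for sperm tails, had 863 dBigH1 reads and a read log2 ratio of 2.16 (2.04 to 2.28). The lowest of the list was FDY at 1.22 (0.21 to 2.12). Of 16 genes in pericentromeric heterochromatin, 11 were at least 1.5-fold higher and 1 was lower, with a list median of 0.83 (counting SD 0.03) and percentile 100. Snap25, a SNARE gene, was the highest by the RPKM ratio, at 1.60 on reads (1.56 to 1.65). RpL38 was the lowest, at -0.96 on 3 dBigH1 reads (-3.28 to 0.67).

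By chromosome, the median ratio of autosomal heterochromatin scaffolds (74 genes) was 1.07 above that of arms 2L, 2R, 3L and 3R (counting SD 0.04). The small chromosome 4, with 93 genes, was 0.61 above (0.03), the Y, with 12 genes, 1.11 above (0.12) and the unplaced scaffolds, with 145 genes, 1.75 above (0.04). The 13 genes of X heterochromatin had a median 0.51 above the median gene. Median dBigH1 RPKM was 5.99 in autosomal heterochromatin, 5.09 on chromosome 4 and 4.25 on the arms, where input RPKM was 5.91, 6.38 and 8.60. On the Y it was 2.51 against an input of 2.28. The arms lay close together, from -0.04 on 2R to 0.06 on 2L relative to the median gene.

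**Figure D2:**
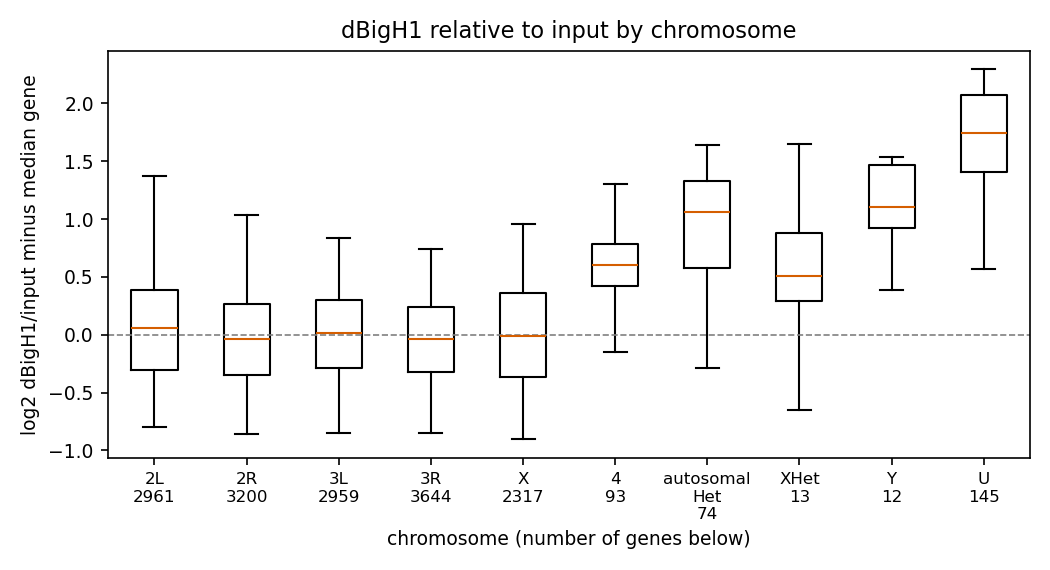
Log2 dBigH1/input ratio minus the median gene (vertical) per chromosome group, with the number of genes under each name. Orange lines are medians, boxes quartiles and whiskers the percentiles 5 and 95 of genes. Chromosome 4, the heterochromatin scaffolds, the Y and the unplaced scaffolds (U) lie above the arms.

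With a pseudocount of 1, the median of the X differed from that of the autosomal arms by -0.001 (counting SD 0.01). Males carry 1 X, and its genes had lower RPKM than the arms in both libraries, with a median input RPKM of 4.74, or 0.55 of the arms, and a dBigH1 RPKM of 2.17. The position of the X depended on the scale. Without a pseudocount the difference was -0.12. The median ratios of the X and the arms were negative, and a pseudocount of 1 shrinks ratios more where RPKM is low. It therefore moved the X up relative to the arms. On the MAnorm score the difference was 0.46, so no direction is given for the X.

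Genes of the early germline were near the median gene. Of 21 such genes, 5 were at least 1.5-fold higher and 1 lower, with a list median of 0.16 (counting SD 0.05) at percentile 93.9. bam, the switch from spermatogonial division to differentiation, was at -0.02 (-0.74 to 0.63) and its partner bgcn at -0.48 (-0.90 to -0.08). Their co-factor tut, listed as CG32364, was at 0.79 on 19 dBigH1 reads, with a lower bound just below 0 and an upper bound of 1.51. mei-P26 was at 1.14 (0.96 to 1.32), vas at 0.32 (0.08 to 0.56) and nos at 0.01 (-0.51 to 0.50). chinmo was the highest of the list by the RPKM ratio, just above mei-P26, and had a read ratio of 1.13 (1.03 to 1.23). CycB was the lowest, at -0.77 (-1.38 to -0.22). The 20 cyst cell and hub genes had a median of 0.12 at percentile 91.1. Their extremes by the RPKM ratio were shg, with a read ratio of -0.15 (-0.51 to 0.18), and ci on chromosome 4, at 0.72 (0.46 to 0.97). The lowest read ratio was that of os, at -0.36 (-1.19 to 0.38).

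Spermatocyte and spermatid genes lay within the limits of random lists matched on mean signal. The 13 meiotic arrest genes, which act in the testis-specific tMAC and tTAF complexes, had a median of -0.09 at percentile 48.6. Among them can was at 0.79 (0.32 to 1.23), aly at 0.27 (-0.41 to 0.89) and mip40 at -1.33 (-2.67 to -0.25). Of 43 late spermatogenesis genes, 4 were at least 1.5-fold higher and 10 lower, with a median of -0.21 at percentile 7.03. When random lists were matched on input RPKM the percentile was 0.19, which is below the limit. Mst77F, a protamine-like chromatin protein, was the highest by the RPKM ratio, with a read ratio of 1.40 (0.88 to 1.89). On reads djl was slightly higher, at 1.42 (0.70 to 2.09), and tomboy20 was at -3.01 on 1 dBigH1 read (-8.33 to -0.49). The 22 piRNA pathway genes had a median of 0.06 at percentile 76.4. Lowest by the RPKM ratio was del, at -0.62 on reads (-1.24 to -0.05). Highest was AGO3, also in the pericentromeric list, at 1.23 (1.17 to 1.30).

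Genes of tissues other than the germline were used for comparison. The 23 neuronal genes had a median of 0.50 (counting SD 0.03), with 8 at least 1.5-fold higher and none lower, at percentile 100, and at 98.3 and 99.1 with matching on input RPKM and on length. fne, an RNA-binding protein gene of neurons, was the highest at 1.76 (1.65 to 1.87), and futsch was at -0.16 (-0.37 to 0.05). Snap25 belonged to this list and to the pericentromeric one. The 21 muscle genes had a median of 0.29 (counting SD 0.06) at percentile 99.8, which became 94.3 with matching on input RPKM, from up at 0.89 (0.55 to 1.21) to Mlc1 at -0.29 (-0.90 to 0.27). With RPKM of at least 5 in both libraries the muscle median was 0.03 relative to the genes left, at percentile 70.1. The 41 Hox genes and Polycomb targets had a median of 0.20 (0.04) at percentile 99.95, but 59.5 with matching on input RPKM and 85.9 with matching on length. Their extremes by the RPKM ratio were oc, at 0.75 on reads with a lower bound of 0.49, and ind, at -1.09 (-2.43 to -0.01). The 179 odorant, gustatory and ionotropic receptor genes had a median of 0.05 (0.03) at percentile 99.7, and at 2.12 with matching on input RPKM, so their side depended on the matching. Ir93a was at 1.82 (1.61 to 2.02) and Gr58c at -2.28 on 3 dBigH1 reads (-4.58 to -0.70).

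Ribosomal protein genes lay below random lists matched on mean signal or length, but not on input RPKM. Of 90 genes, 19 were at least 1.5-fold lower and 5 higher, with a median of -0.24 (counting SD 0.05), below all random lists matched on mean signal. The percentile was 2.40 with matching on length and 9.77 with matching on input RPKM, which ends the call. RpL40 was at -1.46 (-2.93 to -0.30) and RpS19a at 1.75 (1.14 to 2.34). The 15 heat shock genes had a median of -0.08 at percentile 7.97. By the RPKM ratio Hsp26 was the lowest, at -0.89 on reads (-2.05 to 0.07). Hsp70Ba, which has near-identical copies, was the highest, at 0.70 (0.29 to 1.10). The 23 accessory gland genes, from a tissue dissected away, had a median of -0.09 at percentile 18.8, and the 21 chorion and vitelline genes -0.14 at percentile 46.7, which became 2.04 with matching on input RPKM, below the limit. On the MAnorm score those 2 medians turned positive, at 0.10 and 0.30. Their extremes were Acp54A1 at 1.22 (-0.37 to 2.56), Acp62F at -1.82 on 2 dBigH1 reads (-4.90 to 0.09), Cp16 at 0.97 (-0.12 to 1.93) and the yolk protein gene Yp2 at -3.35 on 1 dBigH1 read (-8.67 to -0.83).

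Short RNA genes were limited by depth. The 230 tRNA genes had a median of 2 dBigH1 reads, and for 219 of them the interval spanned the median gene. Their list median of 0.45 (counting SD 0.09) was at percentile 4.18, but at 100 with matching on input RPKM. On the MAnorm score it was -0.28, at percentile 0, so the side of this list depended on the matching and the scale. The 161 snoRNA and snRNA genes, also with a median of 2 dBigH1 reads, had a list median of 0.56 (0.10) at percentile 100, and at 72.7 with matching on length. With at least 10 dBigH1 reads the median was 1.13 at percentile 72.2, which ends the call. Their highest and lowest members rested on 1 to 5 dBigH1 reads. The highest by the RPKM ratio was snoRNA:Me28S-G2703b, which has no symbol in the table, at 3.90 on 5 dBigH1 reads (1.53 to 6.58). Since only genes with at least 1 dBigH1 read were listed, the medians of both lists are biased upward.

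**Figure D3:**
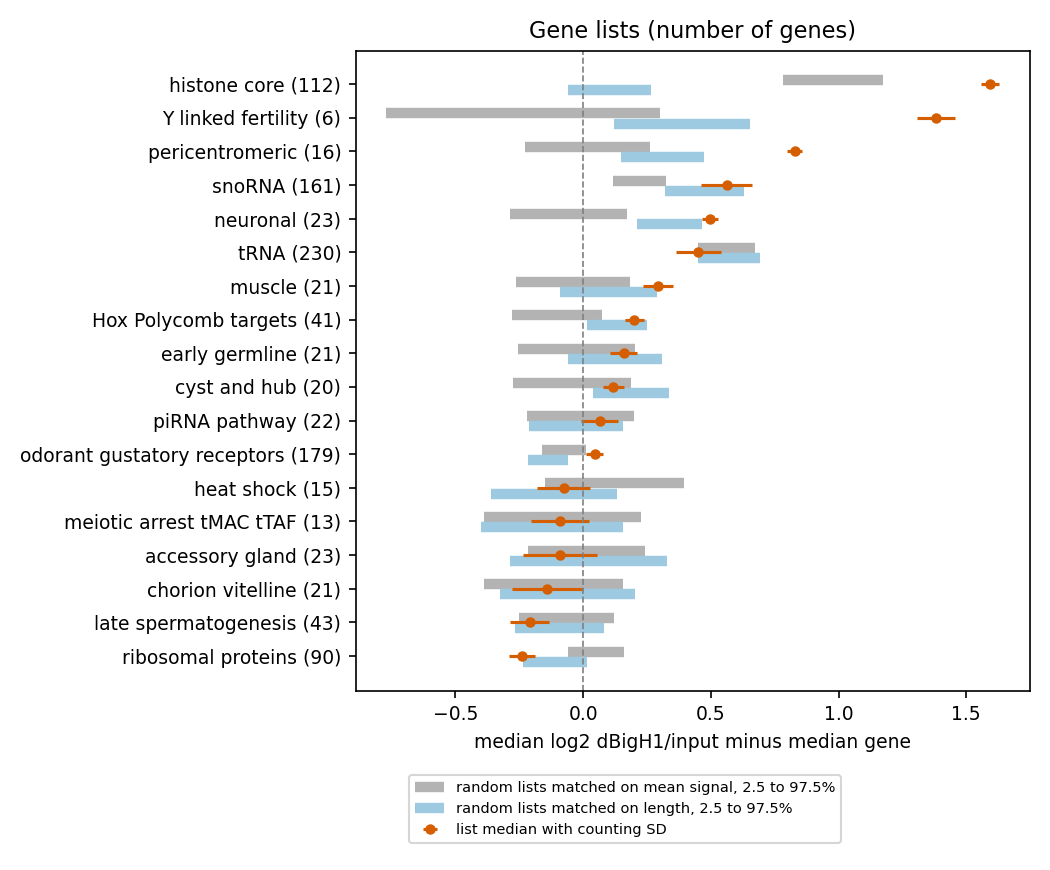
Median log2 dBigH1/input ratio minus the median gene for 18 gene lists (number of genes in brackets). Red points are list medians with the counting SD, grey and blue bars the central 95% of 10000 random lists matched on mean signal and on gene length. Histone, Y-linked, pericentromeric and neuronal lists lie above both ranges, at 1.59, 1.38, 0.83 and 0.50, as do the muscle and receptor lists at 0.29 and 0.05.

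Of the 18 lists, 8 lay above random lists matched on mean signal and 1 below. Histone, Y-linked, pericentromeric and neuronal genes, 4 lists, stayed above with all 3 matchings, and no list stayed below with all 3. For the histone list, with its clustered copies, the members are not separate loci as those of random lists are. Members of the Y-linked list also share a chromosome, and those of the pericentromeric list share a type of region, unlike random lists. Each matching was made separately, so no list was matched on length and input RPKM together.

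The ratio was also compared with gene length and input signal, which library preparation and RPKM scaling can bias. Across genes, which are not independent replicates, Spearman's rho with gene length was 0.08 and with input RPKM -0.36. The relation to length was not monotonic. On the autosomal arms the shortest genes (31 to 495 bp) had a median of 0.34 above the median gene on a median of 3 dBigH1 reads, genes of 1817 to 2358 bp were at -0.17, and genes longer than 11659 bp were at 0.29 on a median of 328 dBigH1 reads. Restricted to genes with an RPKM of at least 5 in both libraries, rho with length turned to -0.18.

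**Figure D4:**
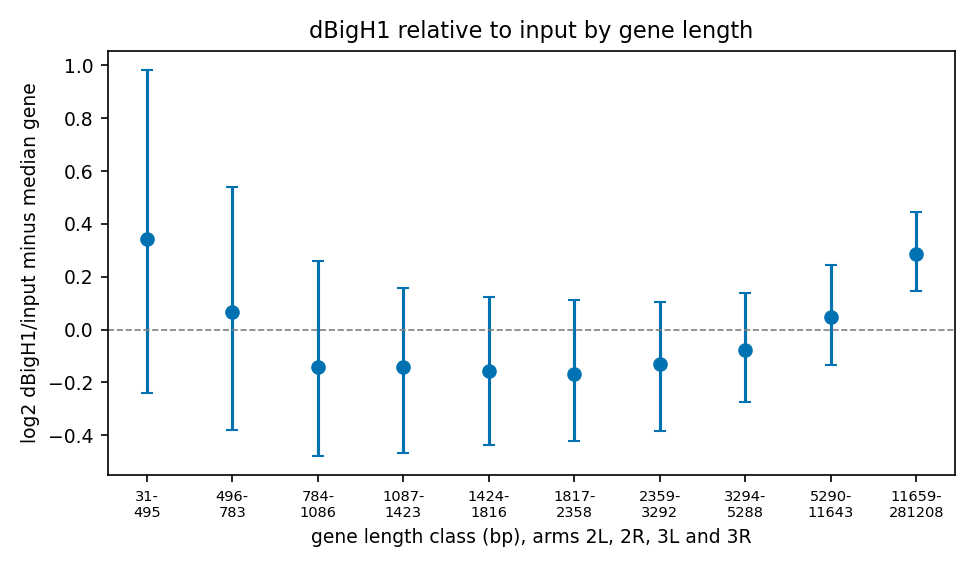
Log2 dBigH1/input ratio minus the median gene (vertical) for 10 classes of gene length in bp (horizontal) on arms 2L, 2R, 3L and 3R. Points are medians and bars quartiles of genes. The medians fall from 0.34 in the shortest class to -0.17 and rise to 0.29 in the longest.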

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

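The alternatives with a read minimum, non-overlapping genes, no pseudocount, length-matched chromosome differences and summed reads were chosen after seeing the data. Counts of genes beyond 1.5-fold, 444 higher and 10942 lower, became 1986 and 1780 with centring on the median gene, 1280 and 869 with centring and at least 10 dBigH1 reads, 1229 and 1054 with centring among genes overlapping no other, 285 and 6403 with a pseudocount of 5, 171 and 5795 at 2-fold, and 3742 and 4221 on the MAnorm score taken at face value. An RPKM of at least 5 in both libraries left 303 higher and 1153 lower of 3750 genes, or 20.8% higher in place of 3.90%. By construction that filter tests fewer genes and removes those with low dBigH1 values. It left 3 lists above random lists in place of 8. Lists below numbered 2 on the MAnorm score and 3 with matching on input RPKM, in place of 1. The Hox and Polycomb list median turned to -0.025 with RPKM of at least 5. The medians of the cyst and hub, piRNA, accessory gland and chorion lists also changed sign, to -0.10, -0.23, 0.28 and 0.22. These medians are relative to the median of the genes left, whose ratio was -0.39 in place of -0.85. The sign changes therefore include a change of reference. The Spearman correlation with length turned to -0.18, and the cause was not tested. The Spearman correlation with input RPKM across genes was -0.43 under that filter and -0.30 with a pseudocount of 0.1.

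Differences from the arms kept their direction for chromosome 4, autosomal heterochromatin, the Y and unplaced scaffolds under every alternative that gave a value. In score units they were 1.56, 2.11, 2.45 and 2.98, without a pseudocount 0.71, 1.25, 1.40 and 2.04, and with summed reads 0.51, 1.27, 1.61 and 1.62. With RPKM of at least 5 they were 0.31, 0.63 and 1.37, and no Y gene remained. Means gave 0.92 for autosomal heterochromatin and 1.61 for unplaced scaffolds. Matched on length without a pseudocount, the Y was at 1.38 and unplaced scaffolds at 2.12. The X was at 0.46 in score units, 0.35 with RPKM of at least 5, -0.12 without a pseudocount, -0.12 matched on length as well, and 0.18 with summed reads. Of the 18 list medians, 14 moved beyond counting error on the MAnorm score, whose unit differs, and 4 with a pseudocount of 0.1. With at least 10 dBigH1 reads 1 moved, the snoRNA list, to 1.13. With RPKM of at least 5, where medians are relative to the genes left, 10 of the 16 with a value moved. In that setting 1 more, the Hox and Polycomb list, reversed. With RPKM of at least 5, the Y-linked and meiotic arrest lists had too few genes for a value, as had the tRNA list with at least 10 dBigH1 reads. The alternatives for called peaks were not run, since regions were not analysed here. No paired analysis was possible because each group had 1 library. Depth limited single genes: 23.3% had fewer than 10 dBigH1 reads.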

Other observations

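The groups and tests in this part were chosen after the data were seen, except the tests of length for the X and for heterochromatin and the test of the score for the X, whose predictions were set before their results. The 40 Su(Ste) copies, the repeats that silence Stellate in the male germline, were all at least 1.5-fold above the median gene, with a median of 1.73, and their summed 1269 dBigH1 reads against 2790 input reads gave 2.02 (95% interval 1.92 to 2.12). Of 13 Stellate copies, 12 were at least 1.5-fold higher, with a median of 1.23. Of 100 5S rRNA genes, 79 were at least 1.5-fold higher and 2 lower, with a median of 1.14, which the restriction to genes with at least 1 dBigH1 read biases upward for such short genes. All 3 groups lay above the median gene on the MAnorm score too, at 3.18, 2.86 and 0.37. These groups were not set against random lists, and reads shared among copies leave single members uncertain. Near the centromeres, genes within 1 Mb of the end of the arm had a median of 0.85 on 3L (16 genes), 0.52 on 2L (46) and 0.50 on 2R (24), but -0.06 on 3R (109) and 0.13 on X (40).

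Among 51 families of genes sharing a symbol prefix, 8 lay above and 8 below the limits of 2000 random lists matched on length, where 1.28 per side are given by chance. Those below included the proteasome genes with the prefix Pros (10 genes, median -0.73), the mitochondrial ribosomal protein genes mRpL (45 genes, -0.52) and mRpS (26 genes, -0.34), and the kinesin-like genes Klp (11 genes, -0.36). The proteasome families Prosbeta (10 genes, -0.36) and Rpn (10 genes, -0.26) lay within the limits, as did the cytosolic ribosomal protein genes RpL (50 genes, -0.23) and RpS (35 genes, -0.23). The highest was the Eig family of ecdysone-induced genes, 11 genes with a median of 0.82. On the MAnorm score Pros, mRpL, mRpS, Klp and Eig kept their directions, at -0.97, -0.90, -0.88, -0.37 and 1.39. Ratios of adjacent genes that did not overlap were correlated across 8713 pairs, with Spearman's rho 0.20 and a highest value of 0.02 in 100 shuffles. Random lists drew scattered genes, so their limits are too narrow for families whose members lie side by side. For such families 1.28 per side understates chance. Families were not matched on input RPKM, a matching that ended the call for the ribosomal protein list. The family calls therefore hold for matching on length only.

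The excess of dBigH1 reads in w and BigH1 stood apart from all other genes with at least 10 dBigH1 reads, and the low input of w, in flies named for a w mutation, enters its 50.7-fold ratio. Input RPKM over the arm median was 1.10 for BigH1 (95% interval 0.94 to 1.28) and 0.70 for w (95% interval 0.61 to 0.79). Input therefore gave no sign of extra BigH1 copies in the flies. For w the arm median may not be the level of the mutant allele, so 0.70 cannot decide on extra copies. Extra copies in the flies would also raise both libraries, so the input level alone does not test the ratio. Sampling was excluded, since the lowest interval bound of both genes was 4.28 above the median gene on the log2 scale. A candidate explanation is a DNA construct with both genes, as w is a common transgene marker, in the dBigH1 library but not in input. Such a construct would give similar excess reads per kb only if it carried the whole of both genes. The excess was 235 reads per kb for w (95% interval 223 to 248) and 304 for BigH1 (275 to 336). Their ratio of 1.29 differs from 1 beyond counting error but lies within 2-fold, a bound set after the excess had been seen. Which parts of each gene a construct would carry is not known, so the ratio cannot decide on it. Binding of dBigH1 at both genes sets no bound on the ratio either. The construct and such binding both stay open.

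The position of the X relative to the autosomes changed sign between the score and the ratio without a pseudocount. The score gap of 0.46 became -0.17 (counting SD 0.03) when X values were raised 1.81-fold to the input level of the arms, so a score trend with mean signal may account for the higher X on that scale. Gene length was excluded for the ratio without a pseudocount, since matching on length left -0.12 of -0.12. With summed reads the X lay 0.18 above the arms, and with RPKM of at least 5 in both libraries 0.35 above. Median dBigH1 RPKM was 2.17 on the X and 4.25 on the arms, so that filter selected X genes with high dBigH1 more strongly. The value of 0.35 therefore gives no direction. No biological explanation was tested, and a lower or a higher dBigH1 level on the X stays open.

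The higher ratio in heterochromatin, on chromosome 4 and on the Y was weighed against length and low input signal. Matching on length left at least 81.1% of the difference in each group. Low input signal alone was excluded for autosomal heterochromatin and chromosome 4, where median dBigH1 RPKM was at least 1.20 times that of the arms. For the Y this comparison cannot decide, since dBigH1 RPKM was 1.16 times that of the X, a difference within counting error. The Y-linked fertility list lay at percentile 99.4 among random lists matched on input RPKM in classes. The median input RPKM of this list was 1.33, and within a class its genes may have had lower input than the genes drawn. The percentile therefore does not exclude low input signal alone for this list. The other Y genes were not matched on input, so low input signal stays open for all Y genes. Reads shared among repeats and GC content stay open and were not tested, so enrichment of dBigH1 in these regions is only a hypothesis.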
